A study of Homo sapiens with 74 samples.

How the data were processed

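The series profiled HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, in 74 libraries. RNA-seq, which counts mRNA fragments, was run on 16 libraries. Ribo-seq, which sequences the mRNA pieces protected by ribosomes from nuclease, was run on 10 libraries. TCP-seq (translation complex profiling) fixes ribosomal complexes on mRNA with formaldehyde before nuclease treatment, so that scanning small subunits also leave footprints, and was run on 16 libraries. Selective TCP-seq adds a pull-down of a tagged protein and was run on 32 libraries. The labels do not spell out the fractions. Sample titles name them SSU and RS. In the 3 FLAG lines the descriptions and count columns of the RS libraries say LSU instead, but 80S for the eIF4E pull-down, whose input says LSU; in the RPL7A-HA line they say RS. SSU is read here as the small-subunit fraction, RS is kept as in the titles, and the fraction behind the TCP-seq libraries is not given in the sources used here.

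The deposited table holds counts of reads per transcript, whole numbers that were not normalized, with 1 column for each of the 74 libraries and 226882 transcripts. Per the submitters' processing notes the authors used cutadapt, STAR and featureCounts on GRCh38.p13; the versions, the strand setting and the annotation release are not given in the sources used here. Per the labels' protocols cells were transfected with 10 nM siRNA, and the Ribo-seq steps followed 48 hours later.

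Transcript identifiers come with exon coordinates but no gene names. A transcript took the name of the RefSeq gene with which it shared at least 0.5 of the joint span, provided that the next gene shared no more than 0.8 as much. The RefSeq table is of assembly GRCh38.p14, a later patch release of the same primary chromosomes, and served for names only. In this way 118376 transcripts (52.2%) matched 43028 genes. Of its 20056 protein-coding genes, 18798 were matched, as were 7653 lncRNA genes. The deposited counts let a read count for every transcript it overlaps: over 1273 nested transcript pairs with at least 1000 counts, 0 had a library with more counts on the contained transcript, and the contained transcript held a median of 0.971 of the larger one's counts. Sums over transcripts therefore count reads several times. So the gene counts are those of 1 representative transcript per gene. It is the one with the most exons among those within 0.1 of the gene's best shared span, with ties decided by the total count. This departs from the plan, which had named sums, and the rule was revised once, from coordinates, before any test was run. Sums, and the transcript with the highest count, were run as alternatives chosen after seeing the data.

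The strand setting was checked on 65 single-exon transcripts that lie inside an exon of the other strand. Their median count density was 0.601 of the enclosing transcript's in RNA-seq and 0.084 in the footprint libraries, so RNA-seq counts of genes that overlap on opposite strands can hold each other's reads. For 51 genes transcripts of both strands shared the span within 0.05 of each other; these genes were left out. The count table holds the 26451 matched protein-coding and lncRNA genes. Transcripts with no matched gene stayed out of library sizes and tests. Mitochondrial rRNA, also left out, took 0.58% to 0.9% of matched counts in RNA-seq, 1.65% to 4.91% in Ribo-seq and 57.6% to 77.92% in TCP-seq.

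Groups and replicate numbers were taken from the sample titles. The labels do not say what the knockdown numbers #1 and #2 stand for; each contrast takes the mean of both numbers minus siControl. SiControl replicates 3 and 4 share their label fields with the triple knockdown and form label set 2 with it; the remaining knockdown libraries and siControl replicates 1 and 2 form label set 1. No label says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicate pairs were checked for duplicates by chi-square over genes with at least 20 counts; chi-square per gene ran from 1.23 to 9.54, so no pair was within sampling noise.

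Gene counts were tested with edgeR 4.0.16 (glmQLFit, robust, and glmQLFTest) in R 4.3.3, after TMM scaling within each assay or fraction and filterByExpr with a minimum count of 10. Adjusted p-values are Benjamini-Hochberg values over the genes of a contrast, called at 0.05. RNA-seq used 16 libraries and 8 residual degrees of freedom. Translational efficiency was the interaction (Ribo-seq change minus RNA-seq change) in 20 libraries with 10 degrees of freedom. The TCP-seq contrast was likewise the TCP-seq change minus the RNA-seq change, in 32 libraries with 16 degrees of freedom. Pull-down against input of the same line and fraction used 32 libraries with 16 degrees of freedom. SSU against RS input used 16 libraries, a term for the tagged line, 1 TMM over all libraries and 11 degrees of freedom. For this last contrast TMM within each fraction was tried first and exchanged for the design as written after its calls had been seen.

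CPM are counts scaled to 1 mega-count on genes per library, without TMM, given as mean ± SD; log2 fold changes are given ± SE. The 28 gene lists, 1 of which holds the 3 silenced genes, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the adjusted p over the lists of a contrast; camera with an estimated correlation and fry stand beside it. A list member rose or fell where edgeR's adjusted p was under 0.05 over all genes tested, and a second count was adjusted over the list alone. Lists with fewer than 3 tested members got no test. A fold against a group at 0 counts was computed against a floor of 3 counts over the group and is a lower bound. Floors cover counting error only, since reads carry no molecular identifiers.

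The text names the 3 silenced genes in each contrast, and genes from the 10 highest and 10 lowest called genes of a contrast with at least 10 CPM and the same direction in both knockdown numbers or replicates. It also names up to 4 members of lists that passed their test. Apart from the list of the silenced genes, all that held with an estimated correlation are given, and only part of those called at the preset alone. Results of a few single genes under this rule are not reported here. SPEN was singled out after its values were seen, as were a few genes named as such. Near-identical copies (HSPA1B and its neighbour HSPA1A, histone genes, ribosomal protein genes with pseudogenes, mitochondrial genes with nuclear copies) can share reads, and their single values are uncertain to that extent.

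Lists, contrasts, the rule for named genes and the alternative settings were fixed before the data were examined. These settings were DESeq2 1.42.0, RLE scaling, no filter and a stricter filter (10 counts in each group mean), each library left out in turn, the replicate number as a block, each knockdown number alone, no label set term, the label set of the contrast alone, and footprints without the RNA-seq change. The step of 0.1 from which a correlation counts as moved was set after the correlations had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Planned checks of untranslated regions and sequence features were not run, because no annotation of the files' build was used here.

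The procedure was tested on simulated data in which 200 genes were changed by 0.5, 1 or 2 on the log2 scale. It recovered 65.7%, 87.9% and 98.5% of them for the double knockdown in RNA-seq (11 of 177 calls were false, 14599 genes) and 38.5%, 64.2% and 83.3% for its translational efficiency. For the TCP-seq contrast of the double knockdown recovery was 4.5%, 23.9% and 48.5% (9 of 60 calls false, 15723 genes). Recovery was 1.6%, 32.2% and 76.3% for the eIF4A1 SSU pull-down, 0%, 15.3% and 39% for the ASCC3 SSU pull-down, 0%, 20.3% and 42.4% for the RPL7A SSU pull-down, and 53%, 93.8% and 100% for the SSU and RS inputs.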

Results

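The series asks how the helicases eIF4A1 and eIF4A2, which unwind mRNA ahead of the ribosome as part of eIF4F, and ASCC3, the helicase of the ASC-1 complex, shape translation in HEK293T cells. The cells received control siRNA (siControl), siRNAs against eIF4A1 and eIF4A2 (the double knockdown, DKD), against ASCC3, or against all 3 (the triple knockdown). Each knockdown had the numbers #1 and #2 with 2 replicates per number and assay. RNA-seq and TCP-seq covered all knockdowns, and Ribo-seq covered siControl, the double knockdown and the ASCC3 knockdown. In a second part, lines carrying eIF4A1-FLAG, eIF4E-FLAG, ASCC3-FLAG or RPL7A-HA gave SSU and RS input and pull-down libraries, with 2 replicates each. Depth is given in mega-counts on genes: the RNA-seq libraries held 10.34 to 17.221 and the Ribo-seq libraries 2.199 to 6.736. The TCP-seq libraries held 0.162 to 1.57 and the inputs 0.361 to 1.445. Pull-downs ranged from 0.077 to 8.149 in SSU and from 0.116 to 5.135 in RS. Between replicates of 1 group, log CPM correlated across genes at 0.994 to 0.996 in RNA-seq and 0.984 to 0.993 in Ribo-seq. The range was 0.532 to 0.86 in TCP-seq, 0.548 to 0.991 in the SSU libraries and 0.721 to 0.983 in the RS libraries.

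The silenced mRNAs fell in every knockdown by RNA-seq. EIF4A1 (chromosome 17, 7572825 to 7579006, plus strand, 11 exons) went from 2170 ± 14.6 CPM (SD, n = 2) in siControl to 186 ± 13.4 and 145 ± 8.32 CPM in double knockdown #1 and #2. In the triple knockdown it went from 1810 ± 33.3 to 132 ± 1.26 and 146 ± 4.59 CPM. EIF4A2 (chromosome 3, 186783577 to 186789881, plus strand, 12 exons) went from 171 ± 2 to 79.9 ± 4.2 and 125 ± 1.12 CPM in the double knockdown, and from 198 ± 6.11 to 70.6 ± 0.0418 and 105 ± 4.62 CPM in the triple knockdown. ASCC3 (chromosome 6, 100508194 to 100881329, minus strand, 42 exons) went from 64.8 ± 3.65 to 23.4 ± 1.16 and 22.8 ± 0.0478 CPM in its own knockdown. In the triple knockdown it went from 96.2 ± 2.38 to 31.5 ± 0.129 and 29.6 ± 0.395 CPM. ASCC3 was higher in the double knockdown, at 138 ± 1.42 and 128 ± 4.74 CPM.

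The footprint assays gave the same genes other levels. In Ribo-seq, EIF4A1 fell from 983 ± 21 CPM to 80.1 and 80.7 CPM in double knockdown #1 and #2, and ASCC3 from 148 ± 8.68 to 48.7 ± 4.53 and 32.6 ± 10.2 CPM in its own knockdown. EIF4A2 went from 91.9 ± 6.99 to 20.9 ± 3.33 CPM in double knockdown #1 but was at 85.4 ± 12.4 CPM in #2. In TCP-seq, counts of a silenced gene were higher than in siControl in several groups. EIF4A2 was at 100 ± 2.58 CPM in siControl, 78.6 ± 3.11 CPM in double knockdown #1 and 6560 ± 3340 CPM in #2, and went from 62.5 ± 15.3 to 27.2 ± 7.52 and 3880 ± 467 CPM in the triple knockdown. ASCC3 went from 362 ± 11.3 to 1110 ± 85.4 and 1020 ± 142 CPM in its own knockdown, and from 43.3 ± 2.75 to 357 ± 141 and 705 ± 290 CPM in the triple knockdown. EIF4A1 was lower in TCP-seq too, going from 400 ± 61.4 to 96.3 ± 18.9 and 98 ± 60.2 CPM in the double knockdown.

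**Figure D1:**
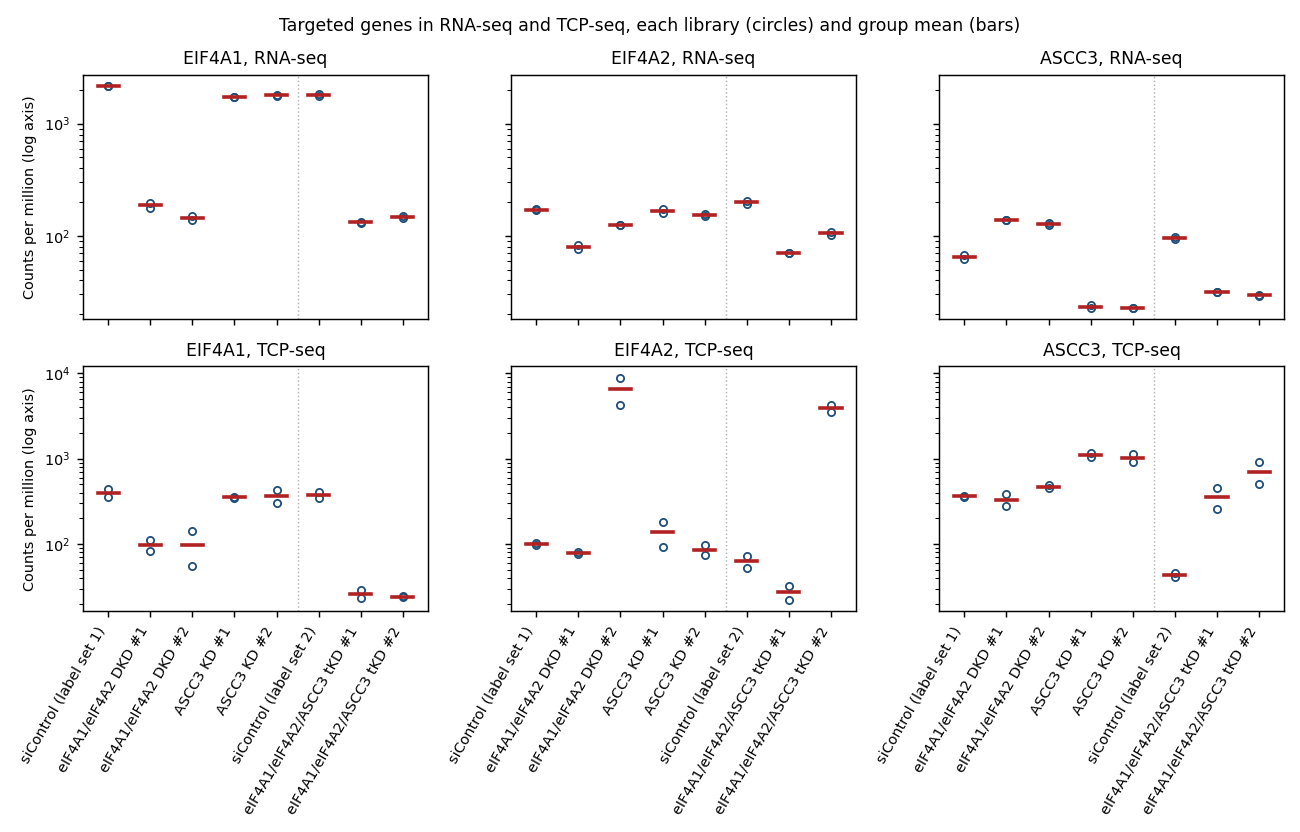
CPM (log axis) of EIF4A1, EIF4A2 and ASCC3 in each knockdown and its siControl libraries, in RNA-seq (top) and TCP-seq (bottom); circles are single libraries and bars the mean of 2. In RNA-seq every silenced gene lies below siControl, while in TCP-seq EIF4A2 reaches 6560 CPM in double knockdown #2 and ASCC3 1110 CPM in ASCC3 knockdown #1.

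The double knockdown changed the abundance of many mRNAs, with 4346 genes higher and 4343 lower of 14907 tested (edgeR, n = 4 against 2). EIF4A1 fell 12.8-fold (log2 fold change −3.68 ± 0.04, adjusted p = 3.8e-74), EIF4A2 fell 1.67-fold (−0.74 ± 0.05, adjusted p = 8.11e-22) and ASCC3 rose 2.1-fold (1.07 ± 0.06, adjusted p = 2.33e-26). All 18 tested p53 target genes rose, a median of 0.84 on the log2 scale (camera adjusted p = 1.48e-19, and 0.000845 with an estimated correlation). CDKN1A, the cell-cycle inhibitor p21 (chromosome 6, 36676490 to 36687337), rose 4.37-fold, SESN1, a stress-responsive regulator of mTORC1, 3.29-fold, and MDM2, the ubiquitin ligase that restrains p53, 2.77-fold. The largest rise under the naming rule was ACTA2, smooth muscle actin, at 9.36-fold (3.23 ± 0.17). ACTA2-AS1 overlaps it on the other strand and its 8.59-fold rise cannot be separated. HSPA1B, an inducible HSP70 gene, fell 9.05-fold (−3.18 ± 0.09, adjusted p = 1.07e-10), followed by VWA1 (3.79-fold) and the kinase MAP2K6 (3.75-fold).

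Cholesterol synthesis genes fell in the double knockdown, 18 of 23 with 0 rising (camera adjusted p = 3.95e-07, and 0.00719 with an estimated correlation). INSIG1, a sterol sensor, fell by 1.03 on the log2 scale and TM7SF2 by 1.16. Of the eIF4F list, EIF4B fell by 0.66 and EIF4E2 by 0.86. Of 14 members 9 fell and 5 rose (camera adjusted p = 3.62e-06, and 0.00679 with an estimated correlation). The call may rest on the silenced eIF4A genes. Ribosomal protein mRNAs fell in 53 of 78 cases and rose in 2 (adjusted p = 9.02e-07 at the preset, adjusted p = 0.437 with an estimated correlation); RPL13A fell by 0.80, RPL10A by 0.71 and RPL3 by 0.60. Nuclear genes of oxidative phosphorylation fell in 49 of 75 cases and rose in 5, and 51 fell when adjusted over the list alone (adjusted p = 1.32e-06, and adjusted p = 0.373 with an estimated correlation). Glycolysis genes fell in 9 of 19 cases and rose in 1 (adjusted p = 0.0349, and adjusted p = 0.429 with an estimated correlation). Of 28 oncogenes reported to depend on eIF4A, 16 rose and 6 fell in abundance (adjusted p = 0.0349, and adjusted p = 0.115 with an estimated correlation; 0.186 with #2 alone). ODC1, the first enzyme of polyamine synthesis, rose by 0.75 on the log2 scale. CCND1, cyclin D1, fell by 0.80, by 0.18 with knockdown #1 and by 1.42 with #2. In the ASC-1 complex, ASCC2 rose by 0.56 and TRIP4 by 0.26 next to ASCC3, 3 of 4 members (adjusted p = 0.0349, and adjusted p = 0.14 with an estimated correlation).

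ASCC3 knockdown changed RNA abundance of fewer genes, 3080 higher and 3238 lower of 14907. ASCC3 fell 2.8-fold (−1.49 ± 0.07, adjusted p = 9.13e-31) and EIF4A1 by 0.30 ± 0.04 on the log2 scale (adjusted p = 3.74e-10), whereas EIF4A2 stood at −0.09 ± 0.05 (adjusted p = 0.131). SYP, the synaptic vesicle protein synaptophysin, rose 3.43-fold (1.78 ± 0.10), TOMM20, a receptor of mitochondrial protein import, 3.21-fold (1.68 ± 0.04) and NTN1, the guidance cue netrin-1, 3.1-fold. MT2A, a metallothionein, fell by 1.78, by 3.23 with #1 and 0.32 with #2. The other ASC-1 members did not pass: ASCC2 stood at −0.11 (adjusted p = 0.0855) and ASCC1 at 0.09 (adjusted p = 0.412), so that 1 of 4 members fell.

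Several gene groups moved together on ASCC3 knockdown at the preset correlation, but of the 6 lists below none held with the estimated one. Genes of the unfolded protein response rose in 13 of 24 cases and fell in 1, or 2 when adjusted over the list alone (adjusted p = 0.00033, and adjusted p = 0.166 with an estimated correlation). PDIA4, a disulfide isomerase of the endoplasmic reticulum, rose 2.08-fold, and SEL1L and DERL1, which act in degradation of its misfolded proteins, 2.1-fold and 1.54-fold. ATF4 targets rose in 16 of 35 cases and fell in 5 (adjusted p = 0.0346, and adjusted p = 0.153 with an estimated correlation). Among them GARS1, glycyl-tRNA synthetase, rose by 0.69 on the log2 scale and ASNS, asparagine synthetase, by 0.62, while DDIT4, an inhibitor of mTORC1, fell by 0.79. With knockdown #2 alone the median of the first list was −0.02 (adjusted p = 0.517) and that of the second −0.05 (adjusted p = 0.517). Of the p53 targets 11 of 18 rose and 3 fell (adjusted p = 0.000978, and adjusted p = 0.11 with an estimated correlation), with CDKN1A up 2.15-fold, SESN1 1.57-fold and XPC 1.41-fold. Nuclear lncRNAs rose in 5 of 7 cases (adjusted p = 0.00112, and adjusted p = 0.11 with an estimated correlation). Glycolysis genes fell in 12 of 19 cases, 13 when adjusted over the list alone (adjusted p = 0.000627, and adjusted p = 0.291 with an estimated correlation). Oxidative phosphorylation genes fell in 34 of 75 cases and rose in 8 (adjusted p = 0.00175, and adjusted p = 0.603 with an estimated correlation).

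The triple knockdown raised 3818 genes and lowered 3923 of 14907 in RNA-seq. EIF4A1 fell 12.9-fold (−3.69 ± 0.04, adjusted p = 1.47e-73), EIF4A2 2.28-fold (−1.19 ± 0.05) and ASCC3 3.12-fold (−1.64 ± 0.06, adjusted p = 4.31e-35). ACTA2 again led the rises at 13.5-fold, with ACTA2-AS1 at 12.1-fold. The p53 targets rose in 17 of 18 cases and fell in 1 (median 1.13, camera adjusted p = 1.79e-30, and 6.4e-05 with an estimated correlation). CDKN1A rose 7.35-fold (2.88 ± 0.07), TP53I3 5.3-fold, PHLDA3, an inhibitor of AKT, 5.01-fold and BAX, an effector of apoptosis, 2.53-fold. Falls under the naming rule were led by HSPA1B (5.71-fold), SPOPL (3.82-fold) and the isocitrate dehydrogenase IDH1 (3.71-fold).

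Cholesterol genes fell in 16 of 23 cases in the triple knockdown and rose in 3, with 17 falling when adjusted over the list alone (adjusted p = 2.92e-09, and 0.00156 with an estimated correlation). INSIG1 fell 2.55-fold and MSMO1 1.89-fold. Mitotic genes fell in 20 of 25 cases (adjusted p = 1.96e-05, and 0.0226 with an estimated correlation). ATF4 targets fell in 18 of 35 cases and rose in 7 (adjusted p = 0.00128, and 0.0226 with an estimated correlation). SLC7A11 fell by 1.83 ± 0.09, DDIT4 by 1.12 and PHGDH by 0.77. The eIF4F list fell in 9 of 14 cases and rose in 5 (adjusted p = 1.09e-09, and 0.00114 with an estimated correlation). This call may rest on the silenced eIF4A genes. S-phase genes fell in 15 of 24 cases and rose in 3 (adjusted p = 0.00153, and adjusted p = 0.0701 with an estimated correlation). Proteasome subunits fell in 20 of 31 cases and rose in 1 (adjusted p = 0.0107, and adjusted p = 0.46 with an estimated correlation), glycolysis genes fell in 12 of 19 and rose in 3 (adjusted p = 0.00153, and adjusted p = 0.306 with an estimated correlation). Other 5′TOP mRNAs fell in 11 of 20 and rose in 6 (adjusted p = 0.022, and adjusted p = 0.275 with an estimated correlation).

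**Figure D2:**
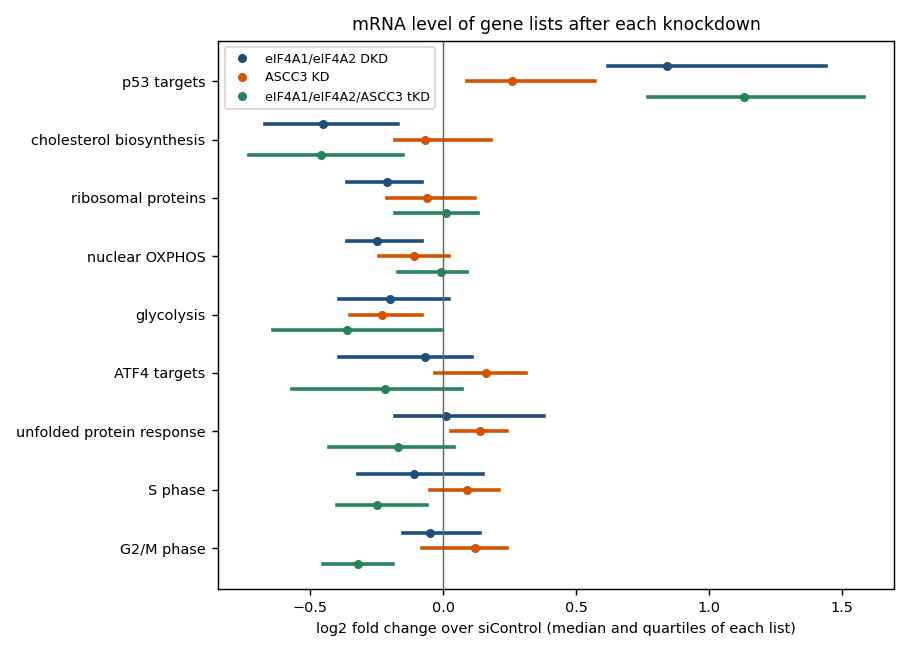
Median log2 fold change in RNA-seq of 9 gene lists in the 3 knockdowns; points are medians and lines run from the lower to the upper quartile of the list members. The p53 targets lie at 0.84 in the double, 0.26 in the ASCC3 and 1.13 in the triple knockdown.

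Translational efficiency, the Ribo-seq change beyond the RNA-seq change, is relative: TMM centres most genes near 0. In the double knockdown it rose for 2191 and fell for 2801 of 14331 genes, and the large changes were mostly falls, with 189 genes more than 2-fold up and 660 more than 2-fold down. EIF4EBP2, a repressor that binds eIF4E, fell 10.5-fold (−3.39 ± 0.16, adjusted p = 6.39e-53) and the cyclin CCNI 9.52-fold (−3.25 ± 0.09). PCBP2, a poly(C)-binding protein (chromosome 12, 53452129 to 53479832), fell 8.94-fold (−3.16 ± 0.06, adjusted p = 2.8e-155) and ODC1 (chromosome 2, 10439968 to 10448327) 8.45-fold (−3.08 ± 0.07, adjusted p = 1.14e-135). Rises under the naming rule were led by NAXD (3.17-fold), RPS15 of the small subunit (2.79-fold, 1.48 ± 0.06, adjusted p = 6.86e-77) and WSB1 (2.77-fold). For the silenced genes, EIF4A1 stood at 0.12 ± 0.06 (adjusted p = 0.143), ASCC3 at −0.16 (adjusted p = 0.147), and EIF4A2 fell by 0.35 ± 0.10 (adjusted p = 0.00362), with −1.04 for #1 and 0.34 for #2.

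Ribosomal protein mRNAs gained translational efficiency in 66 of 78 cases with 0 falling, and in 67 when adjusted over the list alone, at a median of 0.76 (camera adjusted p = 4.89e-64, and 0.00495 with an estimated correlation). RPL37A rose by 1.40 and RPS3 by 1.18 on the log2 scale. Oncogenes reported to depend on eIF4A fell in 12 of 28 cases, 13 when adjusted over the list alone, and rose in 6, at a median of −0.34 (adjusted p = 0.0468, and adjusted p = 0.138 with an estimated correlation). ROCK1, a kinase of the actin cytoskeleton, fell 2.87-fold and ARF6, a small GTPase, 1.55-fold, next to ODC1. This call was lost with Ribo-seq alone, where the median was −0.10 (adjusted p = 0.574). Oxidative phosphorylation genes rose in 49 of 75 cases and fell in 6 (median 0.32, adjusted p = 7.74e-14, and adjusted p = 0.05 with an estimated correlation). With Ribo-seq alone their median was 0.06 (adjusted p = 0.101). Subunits of eIF3, the scaffold of the 43S complex, rose in 9 of 13 cases and fell in 1, or 2 when adjusted over the list alone (adjusted p = 2.52e-06, and adjusted p = 0.05 with an estimated correlation), EIF3L by 1.14, EIF3F by 1.11 and EIF3E by 0.57. Proteasome subunits rose in 18 of 31 cases and fell in 2 (adjusted p = 2.79e-07, and adjusted p = 0.123 with an estimated correlation). Other 5′TOP mRNAs rose in 11 of 20 and fell in 4 (adjusted p = 0.00556, and adjusted p = 0.138 with an estimated correlation), with EEF1G up by 0.82 and TPT1 down by −1.02, but were not called with Ribo-seq alone (median 0.18, adjusted p = 0.171). Stress mRNAs with upstream reading frames rose in 5 of 13 and fell in 1 (adjusted p = 0.0468, and adjusted p = 0.203 with an estimated correlation); with #1 alone the call was lost (median 0.27, adjusted p = 0.153). PPP1R15A, the stress-induced eIF2α phosphatase subunit, rose 2.37-fold.

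On ASCC3 knockdown, translational efficiency rose for 1746 and fell for 2143 of 14331 genes, and few changes were large, 85 more than 2-fold up and 93 more than 2-fold down. ASCC3 itself fell by 0.44 ± 0.11 (adjusted p = 0.00044), EIF4A2 by 0.34 ± 0.09 (adjusted p = 0.0015), and EIF4A1 rose by 0.33 ± 0.05 (adjusted p = 1.98e-08). CIRBP, a cold-induced RNA-binding protein (chromosome 19, 1269352 to 1274773), rose 2.37-fold (1.24 ± 0.10) and HOXA3 2.33-fold. SOCS4, a suppressor of cytokine signalling, fell by 1.68 ± 0.18, by 2.47 with #1 and 0.90 with #2, and NHLRC2 by 1.57, by 2.76 with #1 and 0.39 with #2. The kinase MAP3K2 fell by 1.43. Mitotic genes fell in 11 of 25 cases and rose in 5, with 15 falling when adjusted over the list alone (adjusted p = 0.000396, and adjusted p = 0.319 with an estimated correlation). Oxidative phosphorylation genes rose in 27 of 75 cases and fell in 5 (adjusted p = 2.01e-05, and adjusted p = 0.596 with an estimated correlation). Ribosomal protein mRNAs rose in 23 of 78 cases and fell in 7 (adjusted p = 0.00154, and adjusted p = 0.957 with an estimated correlation), with RPS15 up by 0.83, RPS16 by 0.43 and RPL6 down by −0.60. Glycolysis genes rose in 8 of 19 cases and fell in 1 (adjusted p = 0.0178, and adjusted p = 0.957 with an estimated correlation), ENO1 by 0.29, ALDOA by 0.27 and GAPDH by 0.22. With Ribo-seq alone the last 3 lists were no longer called, at medians of 0.01 (adjusted p = 0.292), 0.05 (adjusted p = 0.166) and −0.11 (adjusted p = 0.174). With #1 alone ribosomal protein mRNAs were at 0.01 (adjusted p = 0.972) and glycolysis genes at 0.09 (adjusted p = 0.431), against 0.22 and 0.25 with #2 alone. Without siControl RNA-seq replicate 1 the number of called genes was 2479 in place of 3889.

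The double and the ASCC3 knockdown were also compared directly, which leaves out the shared siControl libraries. Efficiency was higher in the double knockdown for 2769 and lower for 2738 of 14331 genes. In this comparison ribosomal protein mRNAs were higher in 68 of 78 cases with 0 lower (median 0.65, adjusted p = 1.37e-57, and 0.00762 with an estimated correlation). Subunits of eIF3 were higher in 9 of 13 cases with 0 lower (median 0.31, adjusted p = 1.16e-08, and 0.0249 with an estimated correlation). Other 5′TOP mRNAs were higher in 14 and lower in 6 of 20 cases (median 0.50, adjusted p = 2.43e-05, and 0.0317 with an estimated correlation), EEF1G by 0.79. MDM2 was 2.81-fold and SOCS4 2.76-fold higher, while NT5DC2 was 9.46-fold and PCBP2 8.36-fold lower (−3.06 ± 0.05, adjusted p = 7.08e-173). Of the silenced genes EIF4A1 stood at −0.21 (adjusted p = 0.00129), ASCC3 at 0.28 (adjusted p = 0.00813) and EIF4A2 at −0.01 (adjusted p = 0.967), with EIF4A2 at −0.77 with #1 (adjusted p = 3.77e-06) and 0.75 with #2 (adjusted p = 1.97e-08).

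Across the 14331 genes, which are not independent replicates, the efficiency changes of both knockdowns correlated at 0.451 (Spearman; Pearson 0.505). The siControl libraries are shared, and simulated unchanged groups against them gave 0.547 (0.538 to 0.565 over 20 simulations). The observed covariance was 0.2898 (0.0675 at 10 CPM or more) and the simulated one 0.1665. Split over the 2 siControl replicates, which adds noise, the correlation was 0.271 and 0.211 (covariance 0.0709 and 0.0541).

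**Figure D3:**
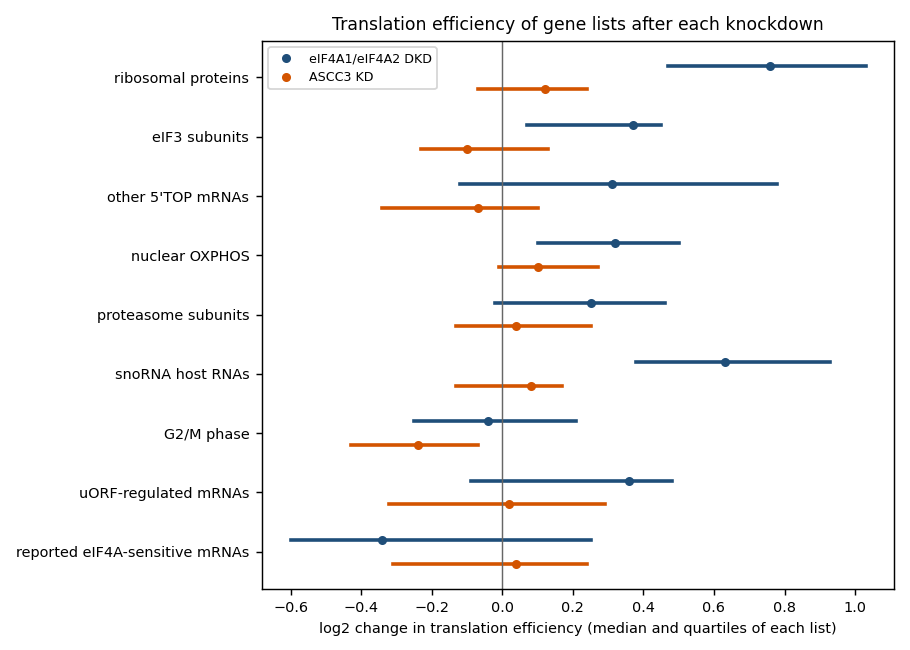
Median change in translational efficiency (log2) of 9 gene lists in the double knockdown and the ASCC3 knockdown; points are medians and lines the quartiles of the members. Ribosomal protein mRNAs lie at 0.76 in the double and 0.12 in the ASCC3 knockdown.

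TCP-seq was read as its change beyond the RNA-seq change, and only 82 genes rose and 114 fell of 16054 in the double knockdown; TMM left the median of all genes at −0.20, and RLE gave 103/84. EIF4A2 rose 11.6-fold (3.54 ± 0.38, adjusted p = 4.87e-06), 0.62 with #1 and 6.46 with #2, EIF4A1 rose 3.08-fold relative to its RNA (1.62 ± 0.22, adjusted p = 5.01e-07) and ASCC3 fell by 1.00 ± 0.23 (adjusted p = 0.0182). Ribosomal protein mRNAs rose in 21 of 78 cases, 43 when adjusted over the list alone with 1 falling, at a median of 0.46 against −0.20 for all genes (adjusted p = 1e-41, and 0.012 with an estimated correlation). RPL21 rose by 1.48, RPL37A by 1.18 and RPS3 by 0.80. Of the p53 targets MDM2 fell by 1.45 ± 0.24 (adjusted p = 3.62e-05); it was the 1 member of 18 to pass, and 5 fell when adjusted over the list alone (adjusted p = 0.000404, and adjusted p = 0.141 with an estimated correlation). RRM2B stood at −2.07 (adjusted p = 0.0591) and GADD45A at −0.97 (adjusted p = 0.102). With TCP-seq alone the median of this list was 0.29 (adjusted p = 0.126). Of the ASC-1 complex only ASCC3 of 4 members passed. The list was called at the preset (median −1.10, adjusted p = 0.0392, and adjusted p = 0.117 with an estimated correlation), but not with #1 or #2 alone (adjusted p = 0.0843 and 0.0661), with no label set term (−0.46, adjusted p = 0.624) or with TCP-seq alone (−0.62, adjusted p = 0.533). UXS1 fell 8.01-fold (90 to 14 counts). Leaving out siControl RNA-seq replicate 1 lowered the number of called genes from 196 to 66.

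On ASCC3 knockdown 8 genes rose and 10 fell of 16054 in TCP-seq (edgeR; median of all genes −0.19; 12/7 with RLE). ASCC3 led at 7.78-fold (2.96 ± 0.23, adjusted p = 1.29e-11), while EIF4A1 stood at 0.05 (adjusted p = 1) and EIF4A2 at 0.19 (adjusted p = 0.988). The nucleoside transporter gene SLC29A2 rose 5.31-fold, CNOT11, of the deadenylase complex, 3.03-fold, and HSPA1B by 1.02 ± 0.16 beyond its RNA (−0.24 with TCP-seq alone, adjusted p = 1). DDX10 fell 7.5-fold, SARNP 4-fold, and DCUN1D1 went from 53 counts to 1. Genes of the unfolded protein response held 0 edgeR calls over all genes, with 1 higher and 7 lower at an unadjusted p under 0.05, and 5 falls when adjusted over the list alone (median −0.36, adjusted p = 0.000577, and adjusted p = 0.0635 with an estimated correlation). The median was 0 (adjusted p = 0.924) with no label set term and −0.19 (adjusted p = 0.915) with TCP-seq alone. PDIA6 stood at −0.84 (adjusted p = 0.0516) and HSP90B1 at −0.58 (adjusted p = 0.358). The ASC-1 complex had a median of 0.78 (adjusted p = 0.000125, and 0.01 with an estimated correlation). This call may rest on the silenced ASCC3, its only called member of 4.

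In the triple knockdown 269 genes rose and 808 fell of 16054 in TCP-seq, with the median of all genes at −0.30 (358/467 with RLE, 1144/1532 with DESeq2). ASCC3 rose 36.8-fold relative to its RNA (5.20 ± 0.27, adjusted p = 2.29e-17) and EIF4A2 by 3.59 ± 0.44, 0.11 with #1 and 7.06 with #2, while EIF4A1 stood at −0.19 (adjusted p = 0.777). That value depended on the transcript counted: summed over all transcripts of EIF4A1 it was 2.26 (adjusted p = 9.37e-06), and on the transcript with the highest count 2.88. Glycolysis genes fell in 10 of 19 cases and rose in 1, at a median of −0.80 (adjusted p = 1.34e-08, and 0.0159 with an estimated correlation). GAPDH fell 3.39-fold (−1.76 ± 0.16), GPI 2.08-fold and ALDOA 1.96-fold. Genes of the unfolded protein response rose in 4 of 24 cases, 8 when adjusted over the list alone, and fell in 1 (median 0.38, adjusted p = 3.26e-06, and 0.016 with an estimated correlation). The chaperone HSP90B1 rose 3.25-fold, HSPA5 3.05-fold and DERL1 2.32-fold. With no label set term the direction turned: the median of this list was −0.21 (adjusted p = 0.399) and HSPA5 stood at −0.99 (adjusted p = 0.518). Ribosomal protein mRNAs rose in 10 of 78 cases and fell in 2 (median 0.08, adjusted p = 0.000321, and adjusted p = 0.514 with an estimated correlation), but with #2 alone they were not called (0.06, adjusted p = 0.111). BICD1 (4 to 37 counts) rested on triple knockdown #2 TCP-seq replicate 1, without which it stood at −1.28.

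SPEN, a large nuclear repressor (chromosome 1, 15847707 to 15940456), was singled out after its values were seen. In siControl TCP-seq it had 3454 ± 1096 CPM in label set 1 and 889.3 ± 7.354 CPM in label set 2 (SD, n = 2). Its level was 59.87 ± 23.43 and 1106 ± 136.5 CPM in double knockdown #1 and #2, 1161 ± 66.47 and 1777 ± 87.68 CPM in the ASCC3 knockdown, and 85.22 ± 19.79 and 24.43 ± 3.677 CPM in the triple knockdown. Beyond its RNA, SPEN fell on average 14.9-fold (−3.90 ± 0.22, adjusted p = 7.74e-16) in the double knockdown and 4.1-fold (−2.04 ± 0.19, adjusted p = 2.7e-09) on ASCC3 knockdown. Of the SPEN counts in siControl TCP-seq, 95.97% to 98.54% lay on a short transcript that contains exons 4 (158 nt) and 5 (201 nt). This share was at most 6.551% in RNA-seq and 11.49% in Ribo-seq. In TCP-seq it was 13.33% to 20% in double knockdown #1 and 14.04% to 45.76% in the triple knockdown. It was at least 77.64% in double knockdown #2 and the ASCC3 knockdown. ASCC3-FLAG pull-downs held 30560 ± 20020 CPM of SPEN in SSU (input 41.08 ± 20.12) and 18920 ± 2694 CPM in RS (input 205.6 ± 227.6), with 99.19% to 99.92% of it on that short transcript. In RPL7A-HA SSU pull-downs replicate 1 had 2167 CPM and replicate 2 had 90.5 CPM.

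**Figure D4:**
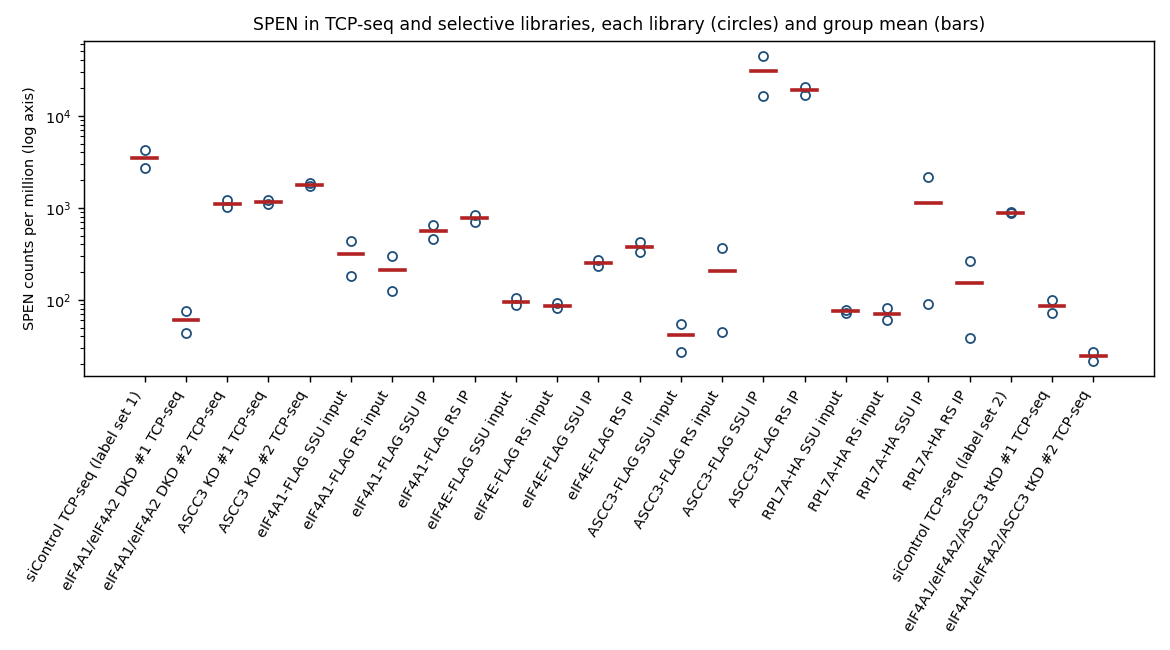
CPM (log axis) of SPEN in the TCP-seq and selective TCP-seq libraries; circles are single libraries and bars the mean of 2. The ASCC3-FLAG pull-downs lie at 30560 CPM in SSU and 18920 CPM in RS, and the triple knockdown lies below siControl.

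Selective TCP-seq asks which mRNAs carry complexes that hold a tagged factor. Pull-down against input gives relative enrichment among mRNAs, since TMM centres most genes near 0. With eIF4A1-FLAG, 1506 genes were higher and 1314 lower in the SSU pull-down than in SSU input, of 11645 tested (n = 2 against 2). EIF4A1 mRNA itself stood at −0.43 in SSU (adjusted p = 0.0756), EIF4A2 fell by 1.25 and ASCC3 stood at 0.26. All 13 mitochondrially encoded mRNAs were lower, at a median of −3.55 (adjusted p = 7.36e-26, and adjusted p = 0.0785 with an estimated correlation). Oxidative phosphorylation genes were higher in 34 of 75 cases and lower in 4 (adjusted p = 3.23e-08, and adjusted p = 0.0785 with an estimated correlation). Ribosomal protein mRNAs were higher in 40 of 77 cases and lower in 7 (median 0.40, adjusted p = 3.33e-08, and adjusted p = 0.0785 with an estimated correlation). Under the stricter filter both calls were lost, at medians of 0.19 (adjusted p = 0.0866) and 0.06 (adjusted p = 0.978). Other 5′TOP mRNAs were lower in 12 of 20 cases and higher in 3 (adjusted p = 0.0002, and adjusted p = 0.0785 with an estimated correlation). KCNC1 was at least 6.85-fold higher (0 to 41 counts).

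In the RS fraction of the eIF4A1-FLAG line 1425 genes were higher and 1610 lower in the pull-down. EIF4A1 mRNA was 3.64-fold enriched there (1.86 ± 0.13, adjusted p = 1.12e-26), from 333 ± 21.5 CPM in input to 1670 ± 203 CPM. Histone mRNAs were lower in 23 of 25 cases and higher in 1 (median −0.82, adjusted p = 4.77e-19, and 0.0199 with an estimated correlation). Proteasome subunits were lower in 22 of 31 cases and higher in 1 (adjusted p = 2.17e-11, and 0.0195 with an estimated correlation). Subunits of eIF3 were lower in 10 of 12 cases (adjusted p = 2.77e-10, and 0.0195 with an estimated correlation). Other 5′TOP mRNAs were lower in 14 of 20 (adjusted p = 5.61e-10, and 0.00786 with an estimated correlation), S-phase genes in 12 of 23 (adjusted p = 1.14e-06, and 0.0295 with an estimated correlation) and mitotic genes in 14 of 25 with 2 higher (adjusted p = 0.000121, and 0.0195 with an estimated correlation). The mitochondrially encoded mRNAs were lower in 13 of 13 cases (median −2.50, adjusted p = 5.42e-14, and adjusted p = 0.0785 with an estimated correlation). Host transcripts of snoRNAs were higher in 5 of 12 and lower in 1 (median 0.65, adjusted p = 0.00377, and adjusted p = 0.166 with an estimated correlation). This call was lost on the transcript with the highest count (0.01, adjusted p = 0.524) and summed over transcripts (0.27, adjusted p = 0.173).

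Pull-down of eIF4E-FLAG, the cap-binding protein, enriched its own mRNA in both fractions. EIF4E (chromosome 4, 98880898 to 98929133, minus strand, 8 exons) was 27.6-fold higher in SSU (4.79 ± 0.37, adjusted p = 8.07e-09) and 33.3-fold higher in RS (5.06 ± 0.40, adjusted p = 1.86e-08). TMTC2 was 21.1-fold higher in SSU and 37.1-fold in RS. The counts of called genes were 2468 higher and 2120 lower in SSU, where the median of all genes was 0.12, and 2132 and 2211 in RS. EIF4A1 mRNA was lower, at −0.99 in SSU and −0.77 in RS, while EIF4A2 stood at −0.08 and ASCC3 at 0.03 in SSU. In SSU, eIF3 subunits were lower in 11 of 12 cases and higher in 1 (adjusted p = 2.34e-07, and adjusted p = 0.148 with an estimated correlation). Histone mRNAs were lower in 21 of 25 and higher in 1 (adjusted p = 2.09e-10, and adjusted p = 0.148 with an estimated correlation). Host transcripts of snoRNAs were higher in 8 of 12 (median 1.08, adjusted p = 0.00037, and adjusted p = 0.148 with an estimated correlation), a call lost on the transcript with the highest count (0.38, adjusted p = 0.545) and summed (0.71, adjusted p = 0.116). Ribosomal protein mRNAs were higher in 37 and lower in 16 of 77 cases (median 0.34, adjusted p = 0.000939, and adjusted p = 0.28 with an estimated correlation), which the stricter filter did not call (0.16, adjusted p = 0.605). The 13 mitochondrially encoded mRNAs were lower here too (median −3.39, adjusted p = 7.17e-14, and adjusted p = 0.148 with an estimated correlation).

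In RS of the eIF4E-FLAG line, where the pull-down columns say 80S and the input columns LSU, snoRNA hosts were higher in 10 of 12 cases (median 1.32, adjusted p = 7.57e-08, and 0.04 with an estimated correlation). Mitotic genes were lower in 17 of 25 and higher in 1 (adjusted p = 3.89e-07, and 0.0103 with an estimated correlation). S-phase genes were lower in 13 of 23 (adjusted p = 1.68e-07, and 0.04 with an estimated correlation) and proteasome subunits in 21 of 31 (adjusted p = 3.83e-08, and 0.047 with an estimated correlation). Subunits of eIF3 were lower in 10 of 12 and higher in 1 (adjusted p = 3.89e-07, and 0.047 with an estimated correlation), other 5′TOP mRNAs lower in 13 of 20 and higher in 4 (adjusted p = 0.000134, and 0.047 with an estimated correlation).

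With ASCC3-FLAG, 761 genes were higher and 599 lower in the SSU pull-down than in input (865/302 with RLE, 892/228 with DESeq2), and the median of all genes was −0.14 in SSU and in RS. ASCC3 mRNA stood at 1.47 ± 1.53 in SSU (adjusted p = 0.613; 48.8 ± 16.4 CPM in input, 140 ± 9.81 CPM in the pull-down). In RS it was 33.4-fold higher (5.06 ± 0.80, adjusted p = 0.000277; from 46.6 ± 7.82 to 1770 ± 333 CPM). EIF4A1 mRNA was lower on its representative transcript, by −0.60 in SSU (adjusted p = 0.049) and −1.37 in RS. Other transcript choices turned this direction: summed over transcripts EIF4A1 was higher, by 0.54 in SSU (adjusted p = 0.00193) and 0.41 in RS (adjusted p = 0.0152), and on the transcript with the highest count by 1.21 and 1.54. Histone mRNAs were lower in 22 of 25 cases in SSU (median −1.16, adjusted p = 6.55e-38, and 0.00623 with an estimated correlation). Ribosomal protein mRNAs were lower in 37 of 77 cases, 46 when adjusted over the list alone (median −0.55, adjusted p = 2.35e-18, and 0.0066 with an estimated correlation). Oxidative phosphorylation genes were lower in 38 of 75 cases, 48 when adjusted over the list alone (median −0.71, adjusted p = 2.56e-17, and 0.0066 with an estimated correlation). Nuclear lncRNAs were higher in 2 of 7 cases (median 0.76, adjusted p = 0.0186, and adjusted p = 0.17 with an estimated correlation). NEAT1, the scaffold of paraspeckles (chromosome 11, 65422798 to 65445540), was 6.34-fold higher and KCNQ1OT1 8.49-fold (9 to 20 counts), while NORAD stood at 0.76 (adjusted p = 0.357). The cannabinoid receptor gene CNR1 was at least 85.8-fold higher (0 to 65 counts). ASCC2, which binds ASCC3 in the ASC-1 complex, was at least 3.53-fold lower (42 to 0 counts).

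In RS of the ASCC3-FLAG line 784 genes were higher and 930 lower (911/599 with RLE, 995/471 with DESeq2). Histone mRNAs were lower in 22 of 25 cases (median −0.99, adjusted p = 2.69e-32, and 0.00585 with an estimated correlation). Ribosomal protein mRNAs were lower in 43 of 77 and higher in 2 (median −0.63, adjusted p = 7.36e-19, and 0.00585 with an estimated correlation), and oxidative phosphorylation genes lower in 40 of 75 and higher in 1 (median −0.67, adjusted p = 7.36e-19, and 0.00585 with an estimated correlation). Proteasome subunits were lower in 21 of 31, 24 when adjusted over the list alone (median −0.97, adjusted p = 3.3e-12, and 0.0171 with an estimated correlation).

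RPL7A-HA tags a protein of the large subunit. In its SSU pull-down 166 genes were higher and 107 lower (189/63 with RLE, 313/58 with DESeq2), and in RS 8 and 41 (133/75 with DESeq2). ASCC3 was 33.4-fold higher in SSU (5.06 ± 0.69, adjusted p = 0.000275), but this rested on pull-down replicate 1, without which it stood at −0.88 (adjusted p = 0.707), while EIF4A1 stood at −0.04 (adjusted p = 0.954). Histone mRNAs were lower in 12 of 25 cases in SSU, 18 when adjusted over the list alone (adjusted p = 7.42e-15, and adjusted p = 0.218 with an estimated correlation). In RS mitochondrially encoded mRNAs were lower in 5 of 13 cases, 13 when adjusted over the list alone (median −1.82, adjusted p = 7.44e-30, and 0.0299 with an estimated correlation). Ribosomal protein mRNAs held 0 edgeR calls of 77 there, with 21 higher and 1 lower at an unadjusted p under 0.05, at a median of 0.17 (camera adjusted p = 2.35e-12, and 0.0299 with an estimated correlation). Oxidative phosphorylation genes and other 5′TOP mRNAs had medians of 0.17 and 0.19, with 1 gene passing of 75 and 1 of 20 (adjusted p = 0.0299 and 0.0338 with an estimated correlation). The second was not called under the stricter filter (0.08, adjusted p = 0.115).

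The SSU enrichments of the tagged proteins were compared by an interaction term. Between ASCC3 and eIF4A1, 614 genes were higher with ASCC3 and 1007 lower, with the median of all genes at −0.19. Scaling turned this split, to 771/626 with RLE and 1102/629 with DESeq2. Ribosomal protein mRNAs were lower with ASCC3 in 53 of 77 cases with 0 higher, 59 when adjusted over the list alone (median −0.92, adjusted p = 3.96e-28, and 0.000902 with an estimated correlation); RPS16 was 3.39-fold lower (−1.76 ± 0.20), RPS14 3.16-fold and RPL38 2.64-fold. Oxidative phosphorylation genes were lower in 48 of 75 (median −1.14, adjusted p = 2.46e-27, and 0.000902 with an estimated correlation). Nuclear lncRNAs were higher with ASCC3 in 3 of 7 cases, 4 when adjusted over the list alone (median 1.90, adjusted p = 1.82e-05, and 0.0186 with an estimated correlation). NEAT1 was 22.9-fold (4.52 ± 0.51) and MALAT1 12.8-fold (3.68 ± 0.42) higher. Nuclear snRNA also took 20.084% and 17.119% of matched counts in the ASCC3 SSU pull-downs, against 5.609% and 4.116% in their inputs and 3.946% and 5.068% with eIF4A1. EIF4A2 was 2.76-fold higher with ASCC3 (adjusted p = 0.0226; 0.46 on the log2 scale, adjusted p = 0.781, without ASCC3 pull-down replicate 1), EIF4A1 stood at −0.17 (adjusted p = 0.765; 1.26 when summed over transcripts, adjusted p = 1.34e-05) and ASCC3 at 1.21 (adjusted p = 0.742). Mitochondrially encoded mRNAs were higher in 13 of 13 cases (median 2.32, adjusted p = 2.23e-14, and adjusted p = 0.123 with an estimated correlation).

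Against eIF4E, 613 genes were higher with ASCC3 and 981 lower (median of all genes −0.22), or 749/577 with RLE and 1077/569 with DESeq2. Here too ribosomal protein mRNAs were lower, in 45 of 77 cases, 57 when adjusted over the list alone (median −0.76, adjusted p = 8.78e-27, and 0.00288 with an estimated correlation), RPL41 3.96-fold and RPL38 3.29-fold. Oxidative phosphorylation genes were lower in 38 of 75 and higher in 1 (median −0.85, adjusted p = 1.55e-18, and 0.00729 with an estimated correlation). Between eIF4A1 and eIF4E 309 genes were higher with eIF4A1 and 286 lower. EIF4E was lower with eIF4A1 (−5.14 ± 0.91, adjusted p = 0.00268), as were TMTC2 (−5.68 ± 0.86) and EIF4A2 (−1.17). Host transcripts of snoRNAs were lower with eIF4A1 in 5 of 12 cases, 10 when adjusted over the list alone (median −0.85, adjusted p = 3.06e-08, and 0.049 with an estimated correlation).

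**Figure D5:**
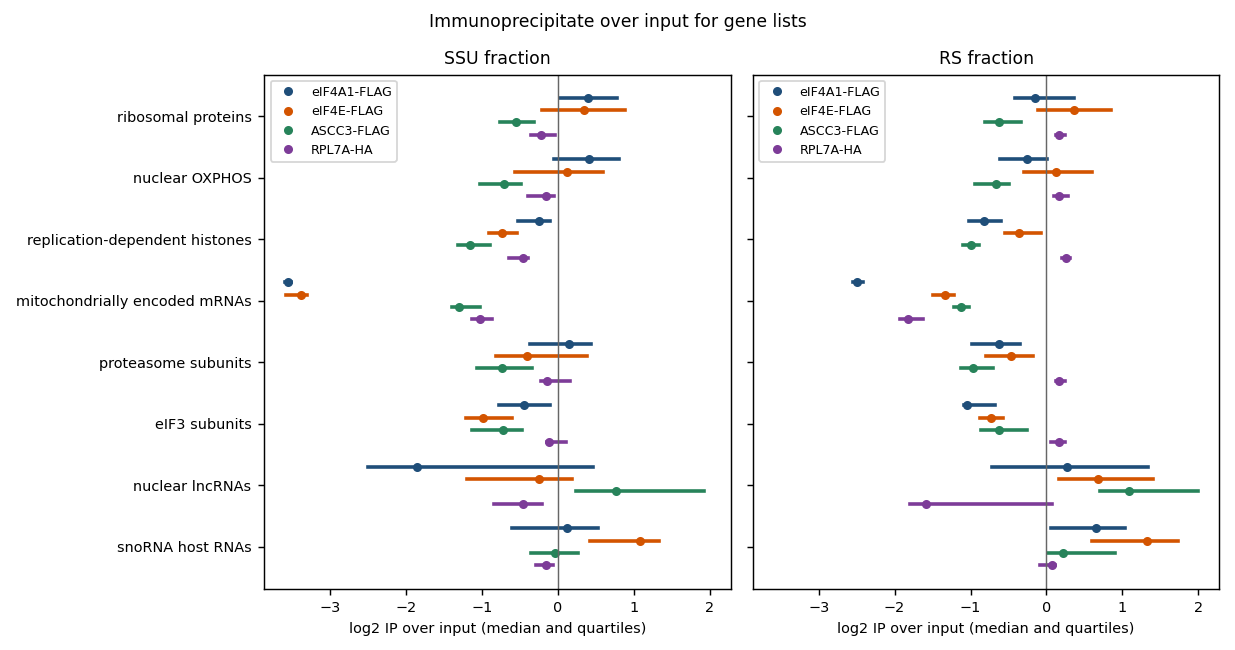
Median log2 enrichment in pull-down over input of 8 gene lists for the 4 tagged proteins, in SSU (left) and RS (right); points are medians and lines the quartiles of the members. In SSU ribosomal protein mRNAs lie at 0.40 with eIF4A1, 0.34 with eIF4E and −0.55 with ASCC3.

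Genes enriched with a tagged protein in SSU were set against the efficiency change on its knockdown, over 11170 genes that are not independent replicates and with no shared libraries. For ASCC3 the Spearman correlation was 0.057 (Pearson 0.049), and for eIF4A1 with the double knockdown 0.072 (0.069). Enriched genes of eIF4A1 and eIF4E overlapped in SSU, 1074 higher in both against 319 for independent lists and 730 lower in both against 239. For eIF4A1 and ASCC3, 34 genes were higher in both against 98 and 126 lower in both against 68, while 127 were higher with eIF4A1 and lower with ASCC3 and 61 the other way.

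SSU and RS inputs of the 4 lines, 8 libraries each, show which RNAs are relatively higher in SSU (origin untested). Of 9141 genes 1503 were higher in SSU and 1500 lower, and 365 were more than 2-fold higher against 48 more than 2-fold lower. Host transcripts of snoRNAs were higher in SSU in 11 of 12 cases (median 1.11, adjusted p = 1.57e-22, and 0.00282 with an estimated correlation), SNHG16 3.49-fold (1.80 ± 0.09), SNHG1 3.34-fold and SNHG5 2.87-fold. Nuclear lncRNAs were higher in 6 of 6 cases (median 1.59, adjusted p = 1.12e-14, and 0.00223 with an estimated correlation), MALAT1 4.96-fold, OIP5-AS1 3.78-fold and NEAT1 2.66-fold. Proteasome subunits were lower in 27 of 30, 30 when adjusted over the list alone (median −0.41, adjusted p = 1.21e-14, and 0.00766 with an estimated correlation). Mitochondrially encoded mRNAs were higher in 11 of 13 (adjusted p = 1.71e-06, and adjusted p = 0.301 with an estimated correlation). Of the stress mRNAs with upstream reading frames 5 of 11 were higher in SSU and 1 lower (median 0.41, adjusted p = 0.00294, and adjusted p = 0.0784 with an estimated correlation). ATF4, whose upstream reading frames hold back its main frame (chromosome 22, 39520564 to 39522685), was 2.93-fold higher (1.55 ± 0.10, adjusted p = 2e-19), ATF5 2.27-fold and UCP2 1.73-fold. EIF4A1 was lower by −0.55 (adjusted p = 1.91e-08), with EIF4A2 at 0.23 and ASCC3 at −0.03. Scaling each fraction by itself gave 945 genes higher and 2585 lower.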

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

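Of the tests in this part, those of siRNA strands, of spread along the mRNA, of ASCC3 in Ribo-seq, of the tagged line, of nascent chains, of background RNA and of depth (thinning) were chosen after the results were seen, the last with its prediction written before the thinned values.

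Differences between effects were flagged where an interaction term called them and the effects had opposite signs. Between the double and the ASCC3 knockdown 347 genes were called in opposite directions in translational efficiency, 100 higher in the double knockdown and 247 higher on ASCC3 knockdown, beside 860 raised and 1064 lowered in both, with shared siControl libraries. The eIF3 list differed by 0.31 (0.37 against −0.10) and other 5′TOP mRNAs by 0.50 (0.31 against −0.07). Between ASCC3 and eIF4A1 in SSU 188 genes were called in opposite directions, 61 higher with ASCC3 and 127 higher with eIF4A1. Ribosomal protein mRNAs differed by −0.92 (−0.55 against 0.40), oxidative phosphorylation genes by −1.14 (−0.71 against 0.41) and nuclear lncRNAs by 1.90 (0.76 against −1.85). Between ASCC3 and eIF4E 185 genes were called in opposite directions, 62 and 123, with ribosomal protein mRNAs at −0.76 (−0.55 against 0.34) and oxidative phosphorylation genes at −0.85 (−0.71 against 0.12). Between eIF4A1 and eIF4E there were 49 such genes, 13 and 36. In RNA-seq depth 1 siControl library stood far from the other 3, at 10.34 against 13.451, 13.736 and 13.763 mega-counts (Dixon ratio 0.909, above its 95% bound for 4 libraries). It was the only flag among 10 tests for a library far from the rest, 5 measures in each of 2 groups of 4 libraries, and chance flags about 1 in 20 groups.

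TCP-seq counts of ASCC3 with both numbers, and of EIF4A2 with #2 but not #1, rose where these genes were silenced, while RNA-seq counts fell. More small subunits along the whole mRNA are argued against for EIF4A2 with #2 and ASCC3 in the triple knockdown. There 0% of 80 pairs of transcript and group (40 transcripts) carried an intermediate part of the excess. The ASCC3 knockdown is undecided. Shorter transcripts carried 1.97 to 4.31 times what shared exon length would give in 4 libraries (siControl 1.17 and 1.21). Yet only 35.7% of 14 pairs were not intermediate. Strands of the siRNA would put the excess at 1 place: 100% of the 80 pairs carried nearly all or almost none of it. In ASCC3 knockdown libraries it was 28.6% to 100%, which decides nothing there. In the triple knockdown 1 of 7 ASCC3 transcripts differed between #1 and #2. A rise along the mRNA also in Ribo-seq is argued against for ASCC3 (at most −1.51 on the log2 scale in its knockdown). For EIF4A2 this could not be decided. Its Ribo-seq stood at 0.04 and −0.26 in the replicates of double knockdown #2, and the 80 pairs hold TCP-seq values only. On the shortest transcript that carried the excess Ribo-seq stood at 0.70 and 1.16 for EIF4A2 (545 nt) and at 0.10 to 1.34 for ASCC3 (852 nt). A local pile-up of another origin may thus remain. No siRNA sequences were used here, and no other biological explanation was tested.

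Each tagged factor was set against its own mRNA in its pull-down, and for RPL7A no enrichment was called (0.32 in SSU, adjusted p = 0.659, and 0.38 in RS, adjusted p = 0.594). The input of the eIF4E line held 5.06 (SSU) and 4.04 (RS) times the EIF4E level of the other lines, but this is argued against as the whole cause, because enrichment over the input of the same line was at least 4.79 on the log2 scale in both fractions. Nascent tagged chains on translating ribosomes would enrich RS above SSU: EIF4E differed by only 0.27 ± 0.53, with both fractions enriched (its RS columns say 80S for the pull-down and LSU for the input), which argues against them as the whole cause. EIF4A1 differed by 2.29 ± 0.23 (adjusted p = 9.79e-15), as nascent chains would give, and ASCC3 by 3.59 ± 1.75 (adjusted p = 0.497), which decides nothing. Carry-over of expression plasmid or a pull-down of the protein's own mRNA may stay open for EIF4E, and neither was tested.

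Ribosomal protein mRNAs were lower with ASCC3 than with eIF4A1 in SSU. The lower depth of the ASCC3 pull-down is argued against: with all these SSU libraries thinned to 102236 counts, the difference was −0.87 to −0.77 in 10 thinnings. Background RNA of a low-yield pull-down cannot be told apart: the list was lower with ASCC3 than with RPL7A (−0.38, fry adjusted p = 0.00752), but the RPL7A pull-down lowered it too (median −0.22) and need not hold the same background, since snRNA took 17.119% and 20.084% of matched counts with ASCC3 against 2.899% and 5.443% with RPL7A. A difference in the mRNAs that both factors meet was not tested and stays open, and the tagged proteins come from separate lines, so that an effect of the line may remain.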

How the results depend on the processing

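Of the tests in this part, sums over transcripts, the transcript with the highest count, TMM within each fraction and thinning were chosen after seeing the data. Where no cause is named, the cause was not tested. A library left out can leave a lone one in its group, which is then assumed to vary like the others. Across settings 6730 values of named genes kept direction and side of the threshold, 350 lost the call, 39 gained one and 82 turned direction. Of the list values 2457 stayed, 211 lost the call and 18 turned direction, 16 of them no longer called. At the depth and spread of these libraries the self-test recovered 48.5% of changes of 2 on the log2 scale in TCP-seq of the double knockdown, and 39% and 42.4% in SSU pull-downs of ASCC3 and RPL7A.

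With an estimated correlation camera called fewer lists: 4 in place of 9 in RNA-seq of the double knockdown, 1 for 8 on ASCC3 knockdown and 6 for 11 in the triple knockdown. In translational efficiency it called 1 for 10, 0 for 4 and 3 for 11 (difference of both). In TCP-seq it was 2 for 4, 2 for 4 and 3 for 7. In SSU and RS pull-downs it was 0 for 5 and 6 for 13 (eIF4A1), 0 for 9 and 6 for 13 (eIF4E), 3 for 10 and 4 for 9 (ASCC3), 0 for 4 and 4 for 11 (RPL7A). For the differences it was 3 for 8, 2 for 8 and 1 for 7, and for the inputs 3 for 13. The numbers for RNA-seq and TCP-seq, and the 13 for eIF4A1 in RS, include the list of the silenced genes, whose RNA change the knockdown itself fixes; on ASCC3 knockdown it was the only 1 left in RNA-seq. Where camera called 0, an unadjusted p under 0.05 held for 2 lists in efficiency on ASCC3 knockdown, and for 4, 5 and 2 in SSU with eIF4A1, eIF4E and RPL7A.

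In TCP-seq of the double knockdown 196 became 1427 with DESeq2, 308 under the stricter filter, 53 and 120 with #1 and #2 alone, 28 without the RNA-seq change and 14 when summed. On ASCC3 knockdown 18 became 456 with DESeq2, 31 with no filter, 11 with #1 alone, 4 without the RNA-seq change and 3 when summed. In the triple knockdown 1077 became 2676 with DESeq2, 347 under the stricter filter, 321 without the RNA-seq change and 119 when summed. As a replicate block, the replicate number gave 27, 4 and 109 genes in these contrasts and 98 in place of 49 for RPL7A in RS, and moved no other count by over 1.5 times. Deviations of same-numbered libraries correlated at −0.148 to 0.393 in RNA-seq, −0.119 to 0.158 between RNA-seq and Ribo-seq, −0.032 to 0.154 between RNA-seq and TCP-seq and −0.028 to 0.351 between pull-down and input. Among siControl and both double knockdown numbers in RNA-seq they were 0.304 to 0.393, a hint at pairs there. Since not every pair passed 0.1 and no label pairs them, the libraries were taken to share only a number.

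Under the stricter filter, which tests fewer genes, SSU and RS pull-downs called 707 of 2820 and 747 of 3035 (eIF4A1), 925 of 4588 and 906 of 4343 (eIF4E), 245 of 1360 and 384 of 1714 (ASCC3), and 119 of 273 for RPL7A in SSU. The differences gave 376 in place of 1621, 513 in place of 1594 and 315 in place of 595. Sums gave 1487 and 1161 for eIF4A1, 1860 and 1111 for eIF4E, and 18 for eIF4A1 against eIF4E. DESeq2 gave 898 for that difference and 208 for RPL7A in RS. Thinning gave 471 (eIF4A1), 546 (ASCC3) and 411.5 (their difference). The correlation of efficiency changes was 0.271 and 0.211 with split controls against 0.451.

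Leaving out each library in turn gave 7082 to 8495 called genes in RNA-seq of the double knockdown, 4193 (without siControl RNA-seq replicate 1) to 6000 on ASCC3 knockdown and 6151 to 7261 in the triple knockdown. For efficiency it gave 4128 to 5039, 2479 (without siControl RNA-seq replicate 1) to 3947, and 4708 to 5462 for the difference. TCP-seq of the double knockdown ran from 66 to 178: 66 and 117 without siControl RNA-seq replicates 1 and 2, 71 without siControl TCP-seq replicate 2, 127 and 115 without RNA-seq replicate 2 of #1 and #2, and 113 and 103 without TCP-seq replicate 2 of #1 and #2. On ASCC3 knockdown it ran from 5 to 31: 6 without siControl RNA-seq replicate 1, 29 and 5 without siControl TCP-seq replicates 1 and 2, 10 and 31 without #1 RNA-seq replicate 2 and #1 TCP-seq replicate 1, and 7 without #2 TCP-seq replicate 2. The triple knockdown gave 766 to 1318.

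The pull-downs gave, for eIF4A1, 1673 to 2466 in SSU (1673 and 1714 without input replicates 1 and 2) and 1601 to 2372 in RS (1884 and 1601 without input replicates 1 and 2). For eIF4E the ranges were 2920 to 3849 in SSU and 2273 to 3527 in RS, lowest without input replicate 2 in both. For ASCC3 they were 822 (without pull-down replicate 1) to 1055 in SSU and 911 (without pull-down replicate 1; 1044 without input replicate 1) to 1347 in RS. For RPL7A they were 157 (without input replicate 2) to 280 in SSU and 15 (without pull-down replicate 2; 24 without input replicate 1) to 72 in RS. Differences gave 1246 to 1673 (ASCC3 and eIF4A1), 1114 to 1619 (ASCC3 and eIF4E) and 269 to 476 (eIF4A1 and eIF4E). The last was 269 and 307 without eIF4A1 SSU input replicates 1 and 2, 369 without eIF4A1 pull-down replicate 2, 364 without eIF4E input replicate 1 and 392 without eIF4E pull-down replicate 2. Inputs gave 2661 to 3019.

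Scaling moved the split of higher against lower calls in TCP-seq, as given above. Scaling also moved it for the ASCC3 and RPL7A pull-downs. The split also moved for ASCC3 against eIF4A1 and eIF4E and, with TMM within each fraction, in the inputs.

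Direction turned, mostly near 0, for these genes. In RNA-seq on ASCC3 knockdown ASCC2 was 0.15 with no label set term. In efficiency of the double knockdown EIF4A1 was −0.07 with #1 and −3.57 with Ribo-seq alone, EIF4A2 0.34 with #2, and ASCC3 0.90 with Ribo-seq alone. On ASCC3 knockdown Ribo-seq alone gave RPS16 −0.15, ALDOA −0.03 and GAPDH −0.11. For the difference EIF4A2 was 0.75 with #2, 0.09 summed, 0.02 on the highest transcript and −0.10 to 0.06 with a library left out, and ASCC3 −0.01 with #1. TCP-seq alone gave EIF4A1 −2.02, ASCC3 0.13 (0.15 with no label set term), MDM2 0.06 and GADD45A 0.21 in the double knockdown, and HSPA1B −0.24 on ASCC3 knockdown. There EIF4A1 was −0.01 with #1, −0.19 with no label set term, −0.15 with TCP-seq alone and −0.06 to 0.21 with a library left out. EIF4A2 was 0 with #2, −0.23 summed, −0.40 on the highest transcript and −0.08 to 0.33 with a library left out, and HSP90B1 0.21 with no label set term. In the triple knockdown BICD1 was −1.28 to 5.42 with a library left out, EIF4A1 0.06 with no label set term, 2.26 summed and 2.88 on the highest transcript, and HSPA5 −0.99 with no label set term.

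In the pull-downs, sums and the highest transcript gave EIF4A1 0.54 and 1.21 (ASCC3, SSU), 0.41 and 1.54 (ASCC3, RS) and 0.36 and 1.08 (RPL7A, SSU). They gave EIF4A2 2.54 and 3.24 (ASCC3, RS), 1.41 and 1.66 (RPL7A, SSU) and 0.91 and 1.39 (RPL7A, RS). ASCC3 was −0.06 under the stricter filter with eIF4A1 in SSU. With eIF4E in SSU EIF4A2 was 0.01 with no filter and −0.19 to 0.11 with a library left out, and ASCC3 −0.01 with RLE, −0.15 under the stricter filter, −0.04 on the highest transcript and −0.08 to 0.24 with a library left out. With ASCC3 in SSU EIF4A2 was −0.76 to 0.61 with a library left out. With RPL7A in SSU EIF4A1 was 0.07 (DESeq2), 0.06 (RLE), 0.05 (stricter filter) and −0.53 to 0.11 (a library left out), EIF4A2 0 (DESeq2), 0 (RLE) and −0.37 to 0.01 (a library left out), and ASCC3 −0.88 without pull-down replicate 1 to 5.79 without replicate 2. Between ASCC3 and eIF4A1 EIF4A1 was 0.11 with DESeq2 and with RLE, 0.48 under the stricter filter, 1.26 summed, 2.17 on the highest transcript and −0.68 to 0.10 with a library left out. Between ASCC3 and eIF4E EIF4A1 was −0.05 to 0.69 and EIF4A2 −0.68 to 0.75 with a library left out. Between eIF4A1 and eIF4E ASCC3 was −0.01 to 0.69 with a library left out, and in the inputs it was 0.07 summed and −0.09 to 0.01 with a library left out.

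Medians of lists turned direction as follows, no longer called unless noted. With #2 alone on ASCC3 knockdown in RNA-seq ATF4 targets were at −0.05 and the unfolded protein response at −0.02, and with no label set term oxidative phosphorylation was at 0.01. Glycolysis was at −0.11 with Ribo-seq alone on ASCC3 knockdown and p53 targets at 0.29 with TCP-seq alone in the double knockdown. In TCP-seq of the triple knockdown the ASC-1 complex was at −0.38 and the unfolded protein response at −0.21 with no label set term, snoRNA hosts at −0.15 with #1 alone, and the ASC-1 complex at −0.16 (without siControl replicate 4) to 2.82 with a library left out, among them −0.09 without #2 replicate 2. Under the stricter filter ribosome quality control was at 0.11 and oxidative phosphorylation at 0.02 (eIF4A1, RS), the unfolded protein response at 0.31 (ASCC3 against eIF4A1) and the proteasome at 0.11 (ASCC3 against eIF4E). With no filter ATF4 targets were at 0.04 (eIF4E, RS) and still called. For snoRNA hosts between ASCC3 and eIF4E the median kept its sign on the highest transcript, at −0.01, but camera, which compares with the other genes, called them higher (adjusted p = 0.000289). In the inputs ribosomal protein mRNAs were at −0.12 with TMM within each fraction and −0.01 to 0.08 with a library left out.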

Other observations

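The test of transcript length in this part was written before its result was seen, and the Ribo-seq check beside it was added after.

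Several groups moved in ways not described above. Host transcripts of snoRNAs gained translational efficiency in the double knockdown in 8 of 12 cases and fell in 1 (median 0.63, adjusted p = 0.00121, and adjusted p = 0.16 with an estimated correlation). Mitochondrially encoded mRNAs rose there in 3 of 13 cases, 6 when adjusted over the list alone (adjusted p = 0.0468, and adjusted p = 0.773 with an estimated correlation). S-phase genes rose in 10 of 24 cases and fell in 5, at a median of 0.06 (adjusted p = 0.0468, and adjusted p = 0.19 with an estimated correlation). Proteasome subunits were lower in the ASCC3 SSU pull-down in 12 of 31 cases, 16 when adjusted over the list alone (adjusted p = 1.2e-07, and adjusted p = 0.0858 with an estimated correlation). Subunits of eIF3 were lower in SSU than in RS input in 7 of 12 cases (median −0.30, adjusted p = 8.76e-05, and adjusted p = 0.0784 with an estimated correlation).

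ASCC3 in siControl TCP-seq stood at 354 and 370 CPM in label set 1 and at 45.2 and 41.3 CPM in label set 2.

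Across 12749 protein-coding genes, which are not independent replicates, translational efficiency in the double knockdown correlated with transcript length at −0.202. This passes the bound of −0.2 set beforehand for shorter mRNAs gaining and longer ones losing. The Ribo-seq change alone correlated at 0.059 and the RNA-seq change at 0.274, so the relation in the double knockdown lies in the RNA-seq term. After that check the test was read as undecided. On ASCC3 knockdown the correlation was −0.254, with the Ribo-seq change alone at −0.106 and the RNA-seq change at 0.177, so there it does not lie in the RNA-seq term alone. For the difference between both knockdowns it was −0.016.

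Of 100 splits of the 16 input libraries into 8 and 8, only the real one, SSU against RS, reached 3003 called genes. The highest other split called 1521 genes and left 14 of the 16 libraries on their own side. The other splits all mix both fractions, so the test cannot decide on chance.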
